A study of Danio rerio with 20 samples.

How the data were processed

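Messenger RNA was sequenced from the livers of 20 male zebrafish (Danio rerio, strain AB JxTu per the labels) in 4 groups of 5: fish aged 1 or 3 years, each age with fish that had no exercise and fish that had exercised in a swim tunnel. The replicate numbers follow only the order of the samples and pair nothing across groups. The labels describe each library as a separate sample and do not say whether each came from a separate fish. Samples are called fish here on that assumption, and the p-values measure only the spread between these samples, which may be technical.

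The deposited counts are whole-number read counts per gene, not normalized. Per the submitters' processing notes the tools were bcl2fastq 1.8.4, STAR 2.4.1d (alignment) and featureCounts 1.4.6-p4 (counting), with genome build GRCz10. Per the labels' protocols the libraries were made with the TruSeq RNA Library Prep Kit v2, which does not mark strand. Reads of overlapping and antisense genes can therefore not be separated. The treatment of reads shared by near-identical genes is not given in the sources used here. The deposited RPKM (reads scaled by gene length and library total, made by the authors from the same counts) were used only for an alternative and for a check. That check showed that the deposited RPKM were divided by library totals that do not belong to the library of each value. Over 1399 genes with at least 1000 counts in every library, the gene length implied by counts, RPKM and the library's own total varied by a median coefficient of variation of 0.14 across libraries. It varied by at most 0.00013 when the total was taken from a list of the 20 totals repeated down the rows of the table. The largest resulting error was 0.59 on the log2 scale. The RPKM were therefore also rescaled, each library to its own total, and both versions were tested. No file column was left without a sample.

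The count table holds 32105 genes with Ensembl identifiers, of which 26269 (81.82%) matched a symbol in the gene name table used here. Symbols are given as in that table, many in the style of human genes, and 4144 genes share a symbol with another gene. Where a shared symbol is named, the identifier follows it, and values of such genes are uncertain where copies share reads. No genome of build GRCz10 was used, so no coordinates are given.

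Counts were tested with edgeR 4.0.16 (R 4.3.3): genes were filtered with filterByExpr on the 4 groups, which left 18079 genes, libraries were scaled by TMM, and 1 model with 4 group means and no covariate was fitted to all 20 samples. Each of 7 contrasts was tested with the quasi-likelihood F-test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. Standard errors were taken from the test statistic. Gene levels are given as CPM, counts scaled to a common library total, here with TMM, unless called plain CPM, which are divided by the total only. Levels on the log2 scale use a prior count of 2.

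Before the data were examined, 36 gene lists were fixed, of pathways, liver functions and markers of cell types and tissues that a liver sample could hold. Of these, 35 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast, and beside it with an estimated correlation and with fry. Members were matched by symbol, by RefSeq synonyms, or by the symbol with its paralog suffix removed. That matching rule was set after the symbol table, but not the values, had been seen. The count of called members is given over all genes tested and also adjusted over the list alone. Named genes follow a rule also fixed in advance: for the 4 single contrasts and the 2 averages, among called genes with a mean of at least 5 CPM over the groups compared and a symbol that is not a placeholder, the 8 rises and 8 falls with the smallest p, and besides these the 4 rises and 4 falls with the largest fold. Where fewer than 5 genes passed, the 3 rises and 3 falls with the smallest p are given as values that did not pass. The interaction has the 10 smallest adjusted p. For each list described, up to 4 called members with the smallest p are named. Some genes that these rules take are not reported here. The lists described, those called by camera with at least 2 called members and the clock list, were chosen after the list results had been seen.

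Total counts ranged from 33046127 to 49579666 per library. On simulated counts with 200 changed genes at the levels and spread of these libraries, over 17653 genes, edgeR recovered 14.1% of genes changed by a factor of 2 and 58.3% of those changed by a factor of 4 in the exercise comparison at 1 year. It made 2 false calls there, and DESeq2 made 28 over 18079 genes. Each gene was drawn independently, without differences between libraries that many genes share, so these figures need not hold for the real libraries.

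Alternatives set before the data were examined were RLE size factors, no low count filter, a stricter filter (at least 1 CPM in 10 of the 20 samples), DESeq2 1.42.0, limma-voom and 1 surrogate variable (sva 3.50.0). Also set then were the pancreas and erythrocyte lists as 2 covariates, limma-trend on log2(RPKM + 1) for genes with a mean RPKM of at least 0.5, the 2 groups compared alone, and each library left out in turn. Chosen after seeing the data were the intestine and pancreas lists as 2 covariates, the fit without the libraries with over 100 plain CPM of the intestinal gene FABP2, the rescaled RPKM, and, for correlations of effects, each library left out. For chance, 100 of the 126 splits of the 10 fish compared were refitted, the real one included, or 100 draws of labels within each age or exercise group for the averages and the interaction. Correlations across genes used differences of mean log2 CPM. Pairs of contrasts with a shared group were set beside 1000 simulated sets of unchanged groups, made by shuffling the deviations of whole fish.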

Results

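Livers of 20 male zebrafish were compared by RNA sequencing in a 2 x 2 design of age (1 or 3 years) and exercise (none, or swimming in a swim tunnel, a flow chamber in which fish swim against a current), with 5 fish per group. Total counts per library were from 33046127 to 47169864 in the resting and from 37276700 to 49579666 in the exercised fish of 1 year. They were from 34398915 to 47150197 in the resting and from 33067760 to 41297161 in the exercised fish of 3 years. Between 20891 and 23404 genes were detected per library. The 10 most abundant genes took from 16.0% to 30.2% of the counts. Within groups the Spearman correlation of log2 CPM between libraries ranged from 0.817 to 0.97, and no pair of libraries was identical.

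The libraries held varying amounts of transcripts known from other organs. FABP2, the intestinal fatty acid binding protein, was above 100 plain CPM in 7 libraries. These were resting 1-year replicate 5 (3480 CPM), exercised 1-year replicates 3 and 4 (282.5 and 3306 CPM), resting 3-year replicate 3 (504 CPM) and exercised 3-year replicates 1, 2 and 5 (2713, 877.7 and 2449 CPM). In the other 13 it was at most 5.73 CPM. The first principal component, 43.6% of the variance, held these 7 libraries between 10.6 and 150.9 and the other 13 between -84.6 and -2.3. Trypsinogen prss1, the most abundant exocrine pancreas gene of its list, ranged from 1.78 to 25400 plain CPM, and the haemoglobin gene hbaa1, the most abundant erythrocyte gene, from 16.2 to 260 plain CPM. The pancreas list had a median log2 fold change of -1.97 in the exercise effect at 1 year, with 0 of 30 members above 0, and was not called (camera adjusted p = 0.279). Its mean log2 CPM was 6.66 at rest and 6.8 after exercise, so on average over libraries it was not lower. In the resting 1-year group prss1 was at 25400 plain CPM in replicate 4 and at 37.9 and 62.2 in replicates 1 and 3. In the exercise effect at 3 years the list had a camera adjusted p of 0.00223 (median -0.66, adjusted p = 0.628 with an estimated correlation), and neither contrast had a called member. Along the second component, 10.8% of the variance, the 1-year fish lay between -3.9 and 62.8 and the 3-year fish between -74.3 and -2.0. The yolk protein genes that oestrogen drives in female liver were low, with vtg1 at most 2.68, vtg2 at most 6.14 and vtg5 at most 77.9 plain CPM, in these samples labelled male.

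**Figure D1:**
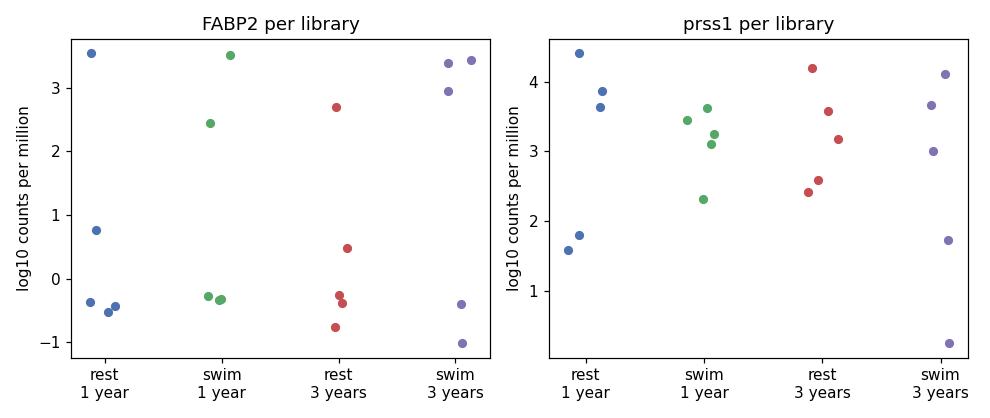
Plain CPM (log10 axis) of FABP2, an intestinal gene, and prss1, a pancreatic gene, in each of the 20 libraries, by group, 1 point per fish. FABP2 lay above 100 CPM in 7 libraries, from 1 of 5 in either resting group to 3 of 5 in the exercised 3-year group.

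The effect of exercise at 1 year was read from the exercised against the resting 1-year fish. Chaperones and regulators of the endoplasmic reticulum, the compartment of secretory protein folding, were lower after exercise. HSPA5 (BiP), its main chaperone, averaged 636 ± 574 CPM at rest and 72.1 ± 26.3 CPM after exercise (SD, n = 5 each), a log2 fold change of -3.14 ± 0.58 (SE). The stress sensor kinase EIF2AK3 (PERK) fell by 1.94, the secreted factor MANF fell by 2.59, the co-chaperone dnajc3b fell by 1.90 and the ubiquitin ligase SYVN1 fell by 1.19 on the log2 scale. Of 35 measured members of the unfolded protein response list, 11 fell and none rose, or 19 adjusted over the list alone, with a camera adjusted p of 1.03e-17 (adjusted p = 0.328 with an estimated correlation). The median log2 fold change was -1.09 over this list, beside -1.97 over the exocrine pancreas list in the same contrast. Mean log2 CPM was 5.82 at rest and 4.89 after exercise for this list, and 6.66 and 6.8 for the pancreas list. Sterol synthesis transcripts were also lower, with MVD at -4.05 ± 0.68, the synthase HMGCS1 at -3.25 ± 0.73 and FDFT1 at -2.17 ± 0.46. In all, 8 of 25 members of the cholesterol synthesis list fell, or 11 adjusted over the list alone, DHCR7 and NSDHL among them (camera adjusted p = 3.69e-10, adjusted p = 0.635 with an estimated correlation). Higher after exercise were the transcription factors ZBTB16 (log2 fold change 4.44 ± 0.74), FOXO1 (ENSDARG00000099555; 2.67 ± 0.55), which drives gluconeogenic genes, and PPARGC1A (3.42 ± 0.80, or 5.15 without resting replicate 5), a coactivator of mitochondrial genes. The oxygen sensor EGLN3 (3.55 ± 0.68) was higher too. The remaining rises with the smallest p were CLPX (ENSDARG00000029063), limch1b, ZBTB17, ABCC5, SUFU, GTPBP10 and ubap2b, by 0.78 to 1.31 on the log2 scale. Falls of smallest p were PRAF2 (-1.84), RHBDF1 (ENSDARG00000036541; -1.75), MYO18A (ENSDARG00000075752; -1.62), KSR1 (ENSDARG00000030933; -1.36), MAPK14 (ENSDARG00000000857; -1.03), TMEM94 (-1.15) and FNDC3B (ENSDARG00000062023; -1.62). The cytochrome P450 cyp2k31 had a large fall (-4.22 ± 0.72). The complement genes c1qa and c1qc, macrophage products, fell by 1.45 and 1.26, the 2 called members of 29 in the myeloid list (3 adjusted over the list alone; camera adjusted p = 0.00194, adjusted p = 0.989 with an estimated correlation). The skeletal muscle list had a median of -1.49 with 0 called members, also adjusted over the list alone (camera adjusted p = 0.0411, adjusted p = 0.989 with an estimated correlation). In all, 249 genes were higher and 266 lower among 18079 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, smallest 0.000311). Without the 7 libraries with intestinal reads 185 genes were called, 149 of them in common, where 1 of 5 resting and 2 of 5 exercised libraries held such reads. Without resting replicate 1, 2 or 4 or exercised replicate 1, 2 or 3 the count was 249, 283, 281, 304, 240 and 272.

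In the exercised against the resting 3-year fish, no gene passed the edgeR test, with a smallest adjusted p of 0.0609, although 2952 genes had an unadjusted p under 0.05 where 904 would by chance. The rises with the smallest p were KLF8 (log2 fold change 1.46 ± 0.24, adjusted p = 0.0609), GFM2 (0.98 ± 0.19) and GNL2 (0.88 ± 0.18). The falls were the proteasome subunits PSMB5 (-0.73 ± 0.12) and PSMD5 (-0.86 ± 0.15) and thap4 (-1.10 ± 0.20), and none of the 6 passed. Lists with no called member over all genes were still called by camera, among them the cytosolic ribosome (median log2 fold change -0.50, camera adjusted p = 2.12e-20; 70 of 74 members lower adjusted over the list alone). Another was the proteasome (-0.35, camera adjusted p = 2e-12; 18 of 39 lower adjusted over the list alone). With an estimated correlation neither list passed (adjusted p = 0.626 for both). With fry the proteasome passed (adjusted p = 0.0329) and the cytosolic ribosome did not (adjusted p = 0.102). The intestine list had a median of 2.87 in the same contrast (camera adjusted p = 0.021, adjusted p = 0.628 with an estimated correlation). The hepatocyte list had one of -0.59 (camera adjusted p = 7.76e-07, adjusted p = 0.626 with an estimated correlation). The erythrocyte list of 15 members had one of -0.86, with 0 called over all genes or adjusted over the list alone (camera adjusted p = 0.00266, adjusted p = 0.626 with an estimated correlation). Other cell type lists had positive medians and no called member. These were skeletal muscle (1.51, camera adjusted p = 0.000525, adjusted p = 0.626 with an estimated correlation), myeloid cells (0.58, camera adjusted p = 1e-04, adjusted p = 0.626 with an estimated correlation; 2 of 29 higher adjusted over the list alone) and lymphocytes (0.65, camera adjusted p = 0.021, adjusted p = 0.628 with an estimated correlation). Intestinal reads were in 3 of 5 exercised against 1 of 5 resting 3-year libraries. DESeq2 called 456 genes, limma-voom 0, limma-trend 0 on the deposited and 23 on the rescaled RPKM, and edgeR 6 with the stricter filter and 2 without the libraries with intestinal reads. Leaving out resting 1-year replicate 3 or 5, resting 3-year replicate 1 or exercised 3-year replicate 2, 3 or 4 gave 3, 22, 1, 1, 11 and 5 calls.

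Age at rest was read from the resting 3-year against the resting 1-year fish. Transcripts of fatty acid and sterol synthesis were far lower in the old livers. ACACA, the first enzyme of fatty acid synthesis, averaged 1210 ± 773 CPM at 1 year and 28.4 ± 20.4 CPM at 3 years (SD, n = 5 each; log2 fold change -5.41 ± 0.69 SE, adjusted p = 0.000758). FASN, the fatty acid synthase, fell by 6.22, the desaturase SCD fell by 7.04, and the NADPH-producing enzyme PGD fell by 2.21. In the fatty acid synthesis list 8 of 25 members fell and none rose, or 13 adjusted over the list alone (camera adjusted p = 1.26e-10, adjusted p = 0.0188 with an estimated correlation). Of the cholesterol synthesis list 17 of 25 fell, or 21 adjusted over the list alone (camera adjusted p = 1.55e-36, adjusted p = 0.0188 with an estimated correlation), with MVD at -5.54, LSS at -4.75, FDPS at -4.56, MVK at -4.17 and HMGCS1 at -4.67. Mean log2 CPM of the cholesterol synthesis list was 5.59 in resting and 4.53 in exercised 1-year fish, and 3.26 and 2.98 at 3 years. Its falls with age at rest and with exercise at 1 year share the resting 1-year fish. AACS, which activates acetoacetate for lipid synthesis, fell by 5.96. In the unfolded protein response list 10 of 35 fell, or 16 adjusted over the list alone, among them HYOU1 (-3.04), HSPA5 (-2.75), SEL1L (-1.27) and SYVN1 (-1.24) (camera adjusted p = 2.02e-12, adjusted p = 0.232 with an estimated correlation). Mean log2 CPM of this list was 5.82 in resting and 4.89 in exercised 1-year fish, and 4.96 and 4.59 at 3 years. This fall and the one with exercise at 1 year thus share the high level of the same resting 1-year fish. The exocrine pancreas list had a median of -0.73 in the same contrast, and camera, with the opposite sign, did not call it (adjusted p = 0.976). Its mean log2 CPM was 6.66 at 1 year and 7.32 at 3 years. The intestine list had a median of -1.85 and was not called by camera (adjusted p = 0.565). Camera called the myeloid list (median 0.37, adjusted p = 0.0285, 0.926 with an estimated correlation) and the stellate cell and matrix list (0.35, adjusted p = 0.0333, 0.79 with an estimated correlation). Neither had a called member. Genes of the circadian clock moved both ways, with 2 higher and 7 lower of 32, or 4 and 10 adjusted over the list alone (camera adjusted p = 0.0025, adjusted p = 0.146 with an estimated correlation). The clock outputs dbpb and tefa fell by 2.06 and 1.26 and the repressor CRY2 fell by 0.81, while the activator BMAL1 (ENSDARG00000006791) rose by 0.69. The light-responsive gene cry3b (1.55 ± 0.22) and the clock-linked repressor nfil3-5 (2.30 ± 0.57) also rose. Further rises were hamp, the iron hormone hepcidin (3.01 ± 0.80), fgfr4 (2.02 ± 0.35), CYP26B1, which degrades retinoic acid (3.00 ± 0.48), KATNAL1, UCK2, spg11, NBAS, BAZ2B and CDC42BPA (ENSDARG00000016464; 4.24 ± 1.05). The sulfotransferase gene sult3st4 had 4.23 ± 1.13, which rested on resting 3-year replicate 2 (42.3 plain CPM, at most 0.909 in the other 4), and 0.38 without it, not called. The calcium pump ATP2A2 (-1.95) and the secretory pathway genes COPB1 (-1.09), ERGIC1 (-1.62) and PRAF2 (-1.92) fell. In all, 223 genes were higher and 409 lower at 3 years (edgeR quasi-likelihood test, adjusted p under 0.05). Without the libraries with intestinal reads, 1 of 5 in either group, 434 were called, 314 of them in common. Fitted on the 2 groups alone 141 were called. Without resting 1-year replicate 1, 2 or 4 or resting 3-year replicate 2, 3 or 5 the count was 239, 264, 417, 419, 386 and 410.

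**Figure D2:**
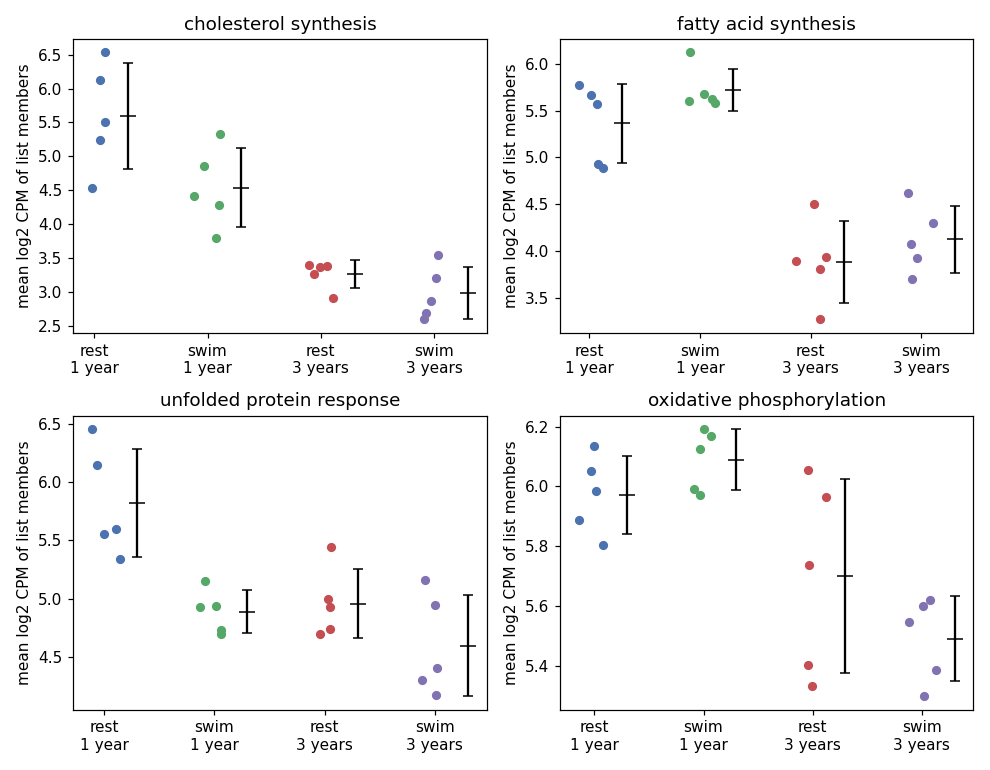
Mean log2 CPM of the members of 4 gene lists in each of the 20 livers, 1 point per fish, with the group mean and SD (n = 5) as a bar. Cholesterol synthesis averaged 5.59 in resting 1-year, 4.53 in exercised 1-year, 3.26 in resting 3-year and 2.98 in exercised 3-year fish.

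Among exercised fish, age was read from the 3-year against the 1-year group, the contrast with most calls of the single ones. Mitochondrial respiratory chain transcripts were lower at 3 years, with 45 of 74 members of the oxidative phosphorylation list down and none up, or 64 adjusted over the list alone (camera adjusted p = 4.35e-24, adjusted p = 0.189 with an estimated correlation). Examples are NDUFA10 (-1.0 ± 0.15), NDUFB2 (-0.81 ± 0.14), UQCRC2 (-0.87 ± 0.15) and the ATP synthase subunit atp5mc1 (-1.11 ± 0.20). Genes of the mitochondrial genome with an MT- symbol took 6.3% to 7.7% of the counts in the 1-year and 3.1% to 6.0% in the 3-year exercised libraries. The hepatocyte list had a median of -0.35 in the same contrast, with 1 of 32 members called lower, or 0 adjusted over the list alone (camera adjusted p = 0.0173, adjusted p = 0.739 with an estimated correlation). Fatty acid oxidation had 12 of 36 members lower, or 23 adjusted over the list alone (camera adjusted p = 3.97e-10, adjusted p = 0.141 with an estimated correlation), including CPT2 (-1.46), BDH1 (-0.90) and the pyruvate dehydrogenase kinases PDK2 (ENSDARG00000020876; -2.11) and PDK4 (-1.20). Proteasome subunits had 15 of 39 members lower and 1 higher, or 25 and 1 adjusted over the list alone, PSMD6 (-1.23), PSMD5 (-1.05), PSMB5 (-0.77) and PSMC4 (-0.62) among them (camera adjusted p = 6.11e-12, adjusted p = 0.189 with an estimated correlation). Fatty acid synthesis had 9 of 25 lower, or 14 lower and 1 higher adjusted over the list alone (ACACA -4.84, ME1 -3.79, ACLY (ENSDARG00000099079) -3.38, SCD -5.89; camera adjusted p = 4.38e-09, adjusted p = 0.0644 with an estimated correlation). Cholesterol synthesis had 11 of 25 lower, or 13 adjusted over the list alone (LSS -4.42, ACAT2 -4.23, FDPS -3.45; camera adjusted p = 5.19e-14, adjusted p = 0.141 with an estimated correlation). Genes of the myeloid list were higher, 15 of 29, or 24 adjusted over the list alone (camera adjusted p = 2.22e-15, adjusted p = 0.141 with an estimated correlation), with c1qa (2.16 ± 0.32), c1qc (1.89 ± 0.28), c1qb (1.81 ± 0.39) and MFAP4 (ENSDARG00000089667; 5.05 ± 0.88). In the antigen presentation list 4 of 20 rose, or 5 adjusted over the list alone, cd74a, cd74b, ciita and mhc2dab by 2.81, 2.35, 2.43 and 5.23 (camera adjusted p = 0.000279, adjusted p = 0.524 with an estimated correlation). The complement genes c4b and c1s.1 rose by 2.23 and 1.68, the called 2 of 31, also 2 adjusted over the list alone (camera adjusted p = 0.00335, adjusted p = 0.689 with an estimated correlation). Libraries with intestinal reads were 3 of 5 at 3 years and 2 of 5 at 1 year. Mean log2 CPM of the antigen presentation list was 5.31, 5.17 and 5.56 in 3-year replicates 1, 2 and 5, which held them. It was 3.61 and 4.16 in 3-year replicates 3 and 4. At 1 year it was 3.75 and 4.75 in replicates 3 and 4, which held them, and from 3.3 to 3.5 in the others. Whether these reads account for the rise of the list was not tested. The skeletal muscle list had a median log2 fold change of 2.88 with no called member, or 14 higher adjusted over the list alone (camera adjusted p = 3.15e-05, adjusted p = 0.454 with an estimated correlation). The lymphocyte list had a median of 1.25 with 1 of 19 members higher, also 1 adjusted over the list alone (camera adjusted p = 0.00047, adjusted p = 0.421 with an estimated correlation). Its mean log2 CPM was 0.7, 1.0 and 1.1 in 3-year replicates 1, 2 and 5, and 0.1 and 0.2 in replicates 3 and 4. At 1 year it was -0.6 and 0.6 in replicates 3 and 4, and from -1.8 to -0.5 in the others.

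Clock genes were also apart between the exercised groups, with dbpb at -3.61 ± 0.33, the smallest p of the named genes (adjusted p = 1.47e-05), while BMAL1 (ENSDARG00000006791), NFIL3, nfil3-5 and cry3b rose by 1.1, 2.51, 4.5 and 2.1. Of 32 clock genes 6 rose and 9 fell, or 7 and 10 adjusted over the list alone (camera adjusted p = 0.0648, not called). Other falls with the smallest p were loxl2a, a collagen cross-linking enzyme (-4.24 ± 0.45, from 228 CPM at 1 year to 12.0 at 3 years), the lipase inhibitor g0s2 (-4.30 ± 0.56), AMT (-1.66), slc39a1 (-1.81), ABHD11 (-3.35) and CKB (ENSDARG00000069752; -2.1). Rises with the smallest p included RHBDF1 (ENSDARG00000036541; 1.77), BCOR (1.36) and utrn (1.31). Among the largest changes were TG, the thyroid hormone precursor thyroglobulin (9.30 ± 2.17), EPX (5.75 ± 1.56), an eosinophil peroxidase, phf20l1 (5.18 ± 1.06), sat2a.2 (-10.96 ± 2.44) and crp1 (-5.59 ± 1.53). TG was at 82.5 and 147 plain CPM in exercised 3-year replicates 3 and 4, between 2.62 and 3.31 in the other 3 of that group, and at most 0.204 in the exercised 1-year fish. The oestrogen responsive list had vtg5, vtg2 and ESR1 among 4 falls (-3.59, -3.92 and -1.05) among its 6 members, and F13A1 (ENSDARG00000045453) rose by 3.40. Adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.00374, adjusted p = 0.0832 with an estimated correlation). In all, 707 genes were higher and 950 lower at 3 years (edgeR quasi-likelihood test, adjusted p under 0.05). Without the libraries with intestinal reads 437 were called, 320 of them in common, and 40 of the 70 genes that the naming rule takes passed. Without exercised 1-year replicate 1, 3, 4 or 5 or exercised 3-year replicate 1 the count was 1034, 866, 2515, 956 and 1025.

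**Figure D3:**
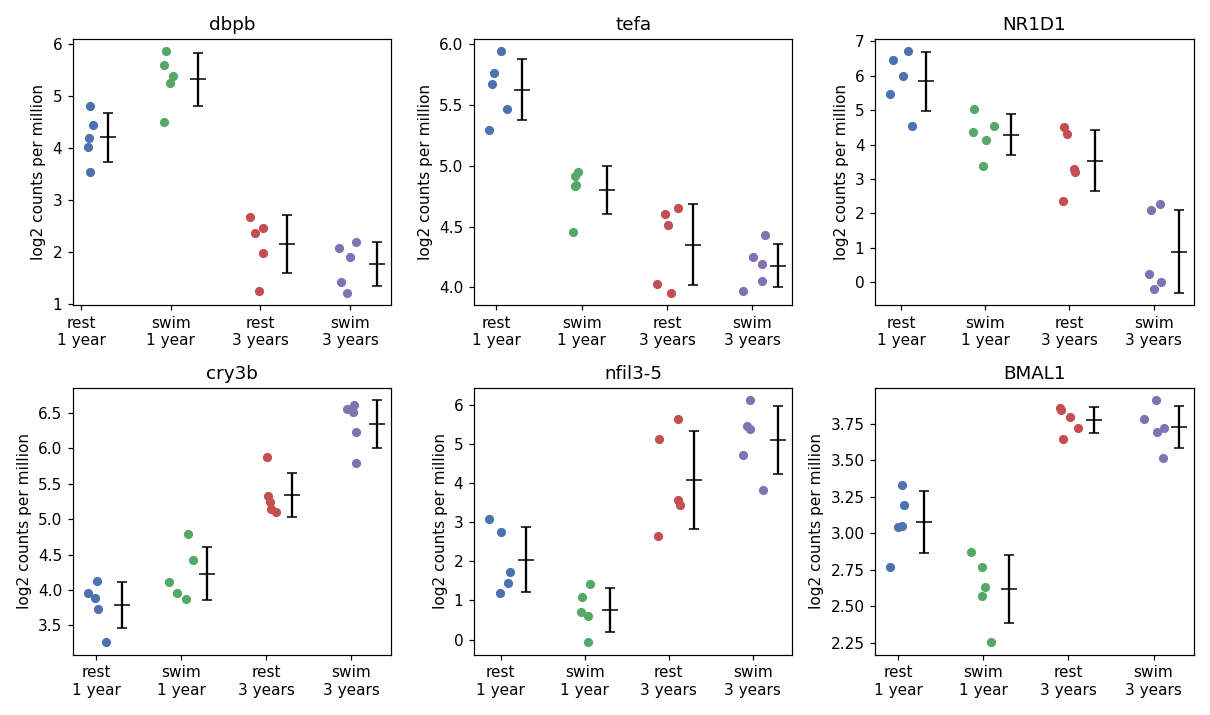
Log2 CPM of 6 clock and clock-linked genes in each of the 20 livers, 1 point per fish, with group mean and SD (n = 5). In the averaged age effect dbpb, tefa and NR1D1, the last chosen after its values were seen, had log2 fold changes of -2.83, -0.94 and -2.70, and cry3b, nfil3-5 and BMAL1 of 1.83, 3.40 and 0.90.

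Averaged over exercise, lipid synthesis and respiratory chain transcripts were lower and transcripts of the myeloid list higher at 3 years. At rest, 0 of 74 oxidative phosphorylation and 0 of 29 myeloid members were called for age, also adjusted over the list alone. Their medians at rest were -0.22 and 0.37 (camera adjusted p = 1.94e-05 and 0.0285, adjusted p = 0.926 for both with an estimated correlation). Camera did not call fatty acid oxidation or the proteasome for age at rest (adjusted p = 0.83 and 0.153). Of 25 cholesterol synthesis genes 19 fell, or 22 adjusted over the list alone (camera adjusted p = 4.1e-34, adjusted p = 0.0273 with an estimated correlation), with LSS at -4.59 ± 0.46, FDPS at -4.00 ± 0.43, MVK at -3.21 and EBP at -3.10. Of 25 fatty acid synthesis genes 14 fell, or 15 adjusted over the list alone (camera adjusted p = 4.48e-14, adjusted p = 0.0066 with an estimated correlation), with ACACA at -5.13 ± 0.48, FASN at -4.95 and SCD at -6.46, and AACS fell by 5.14. The oestrogen responsive list passed with an estimated correlation as well (4 of 6 lower and 1 higher, or 5 and 1 adjusted over the list alone; camera adjusted p = 0.00225, adjusted p = 0.0348 with an estimated correlation). Its members had vtg2 at -3.87, vtg5 at -2.07, ESR1 at -0.82 and F13A1 (ENSDARG00000045453) at 2.72. Oxidative phosphorylation had 45 of 74 members lower, or 62 adjusted over the list alone (NDUFA10 -0.72, atp5mc1 -0.82, COX5A -0.59, UQCRFS1 -0.75; camera adjusted p = 3.51e-20, adjusted p = 0.263 with an estimated correlation). In the myeloid list 14 of 29 rose, or 20 adjusted over the list alone (camera adjusted p = 1.11e-11, adjusted p = 0.203 with an estimated correlation). The genes c1qa, c1qc, cfp and MFAP4 (ENSDARG00000089667) rose by 1.28, 1.17, 1.84 and 2.66. The skeletal muscle list had a median of 1.17 with 0 of 25 called, also adjusted over the list alone (camera adjusted p = 0.00633, adjusted p = 0.649 with an estimated correlation), and the lymphocyte list one of 0.48 with 0 of 19 called, also adjusted over the list alone (camera adjusted p = 0.00633, adjusted p = 0.586 with an estimated correlation). The cholangiocyte list had one of 0.31 with 1 of 13 called, also 1 adjusted over the list alone (camera adjusted p = 0.0118, adjusted p = 0.203 with an estimated correlation). Complement genes made in liver rose in 7 of 31 cases, or 12 adjusted over the list alone (camera adjusted p = 2.44e-05, adjusted p = 0.543 with an estimated correlation). Among them were c7a at 1.95, c4b at 1.66, c9 at 1.36 and c1s.1 at 1.21. In the unfolded protein response list 14 of 35 fell and 1 rose, or 17 and 2 adjusted over the list alone (HYOU1 -2.07, CANX -0.93, ASNS -1.18, SEL1L -0.85; camera adjusted p = 1.69e-07, adjusted p = 0.288 with an estimated correlation). Of 39 proteasome subunits 14 fell, or 23 adjusted over the list alone (PSMD6 -0.83, PSMD8 -0.55, PSMC4 -0.41, PSMB5 -0.38; camera adjusted p = 4.96e-08, adjusted p = 0.331 with an estimated correlation). Fatty acid oxidation had 7 of 36 members lower and 1 higher, or 12 and 2 adjusted over the list alone (PDK2 (ENSDARG00000020876) -1.97, CPT2 -1.07, BDH1 -0.76, PDK4 -0.74; camera adjusted p = 2.44e-05, adjusted p = 0.307 with an estimated correlation). Gluconeogenesis and glycogen genes fell in 3 of 20 cases, or 6 adjusted over the list alone (pck2 -0.84, g6pc1a.1 -0.96, IRS2 (ENSDARG00000037099) -1.88; camera adjusted p = 0.000993, adjusted p = 0.202 with an estimated correlation). Hepcidin (hamp) rose by 3.99 ± 0.59. Of the clock list 5 of 32 rose and 12 fell, or 8 and 15 adjusted over the list alone (camera adjusted p = 0.00317, adjusted p = 0.153 with an estimated correlation), led by dbpb (-2.83 ± 0.22). Falls of smallest p besides were loxl2a (-3.29), ATP6V1C1 (ENSDARG00000035880; -1.69) and ldah (-2.05), and rises included cry3b, BCOR, fgfr4 and UCK2, by 0.87 to 1.83. Besides SCD, large folds were those of EPX (5.19), tas1r3 (5.06), TG (5.03), mhc2dga (4.46), crp1 (-3.53) and sat2a.2 (-6.32, or -10.28 without resting 3-year replicate 1). Without resting 3-year replicate 2 tas1r3 had 2.58, and without resting 3-year replicate 4 TG had 2.84, neither of them called. The taste receptor gene tas1r3 was at 53.2 plain CPM in resting 3-year replicate 2, 29.2 in exercised 3-year replicate 4 and 7.51 in exercised 3-year replicate 1, and at most 1.06 in the other 3-year libraries. In all, 977 genes were higher and 1256 lower at 3 years (edgeR quasi-likelihood test, adjusted p under 0.05). Without the libraries with intestinal reads 1450 were called, 1083 of them in common, and 55 of the 62 genes that the naming rule takes passed.

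With exercise averaged over both ages, the genes that rose included ZBTB16 (3.55 ± 0.50), its paralog zbtb16b (1.71 ± 0.42), FOXO1 (ENSDARG00000099555; 2.24 ± 0.38), PPARGC1A (3.01 ± 0.56) and EGLN3 (2.13 ± 0.45). Also higher were the RNA polymerase I subunit POLR1B (1.32), dnttip2 (0.98), DPH2 (0.85), pho (0.98), GTPBP10 (0.59) and ubap2b (0.58). Endoplasmic reticulum chaperones fell, 9 of 35 in the unfolded protein response list, or 23 lower and 1 higher adjusted over the list alone (MANF -1.67, CANX -0.91, CALR -1.28, SDF2L1 -1.48; camera adjusted p = 7.5e-17, adjusted p = 0.332 with an estimated correlation). The median of this list was -1.09 at 1 year and -0.40 at 3 years. At 3 years alone 0 of 35 were called, or 8 lower and 1 higher adjusted over the list alone. HSPA5 averaged 94.3 CPM at rest and 135.7 CPM after exercise at 3 years. The exocrine pancreas list had a median of -1.32 in the same average, with 0 of 30 members called, also adjusted over the list alone (camera adjusted p = 0.00333, adjusted p = 0.915 with an estimated correlation). Its mean log2 CPM was 6.66 at rest and 6.8 after exercise at 1 year, and 7.32 and 5.19 at 3 years. The hepatocyte list had a median of -0.36 with 0 of 32 called, also adjusted over the list alone (camera adjusted p = 9.81e-05, adjusted p = 0.915 with an estimated correlation). For the erythrocyte list it was -0.42 with 0 of 15 called, also adjusted over the list alone (camera adjusted p = 0.00743, adjusted p = 0.915 with an estimated correlation). The clock repressor NR1D1 fell by 2.06 ± 0.40. Further falls were cyp2k31 (-3.59 ± 0.50), trim35-10 (-1.84), MAF (ENSDARG00000076520; -2.34), slc25a39 (-1.61), ugt5d1 (-1.25), SLC39A7 (-0.73), C18H11orf58 (-0.89), MAPK14 (ENSDARG00000000857; -0.59) and pdzk1ip1 (-0.56). Of the cholesterol synthesis list MVD (-1.93) and NSDHL (-0.86) fell, the called 2 of 25, or 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.2e-09, adjusted p = 0.819 with an estimated correlation). MVD went from 83.3 to 5.04 CPM with exercise at 1 year, but from 1.79 to 2.04 CPM at 3 years. The median of this list was -1.07 at 1 year and -0.30 at 3 years, where 0 of 25 members were called. In all, 181 genes were higher and 172 lower (edgeR quasi-likelihood test, adjusted p under 0.05). Without the 7 libraries with intestinal reads 6 genes were called, 3 of them in common, and 3 of the 33 genes that the naming rule takes passed. Leaving out resting 1-year replicate 1, 2, 3, 4 or 5 gave 186, 216, 212, 162 and 657 calls, and exercised 1-year replicate 1, 2, 3 or 4 gave 187, 157, 198 and 193. Leaving out resting 3-year replicate 3 gave 230, and exercised 3-year replicate 1, 2 or 5 gave 231, 177 and 140.

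The difference between the exercise effects at the 2 ages was tested as an interaction, taken as the effect at 3 years minus that at 1 year. RHBDF1 (ENSDARG00000036541), a regulator of protein trafficking, had the lowest adjusted p (interaction 2.50 ± 0.30 log2, adjusted p = 0.00114), with group means of 10.9 CPM at rest and 3.22 CPM after exercise at 1 year and 6.55 and 11 CPM at 3 years. EIF2AK3 (2.4 ± 0.37), MYO18A (ENSDARG00000075752; 2.1), ACBD3 (2.2), RREB1 (ENSDARG00000063701; 2.14) and SYNE1 (1.68) also differed upwards. The hepatocyte transcription factor paralog hnf4b (-2.16 ± 0.34), with fbxw11a (-2.32), SLC49A4 (-1.50) and rims2b (-3.85), differed downwards. In the unfolded protein response list 3 of 35 had a positive interaction, HSPA5, dnajc3b and DNAJB9 (ENSDARG00000016886), or 12 adjusted over the list alone (camera adjusted p = 0.00057, adjusted p = 0.555 with an estimated correlation). The resting 1-year fish, highest in this list (mean log2 CPM 5.82, from 4.59 to 4.96 in the other groups), enter this contrast too. PSMD5 and PSMB5 were the 2 called proteasome members of 39, both negative, or 7 negative and 1 positive adjusted over the list alone (camera adjusted p = 8.31e-07, adjusted p = 0.555 with an estimated correlation). Cell type lists with no called member had in the same contrast medians of 2.59 for skeletal muscle (camera adjusted p = 1.41e-05), 1.26 for myeloid cells (camera adjusted p = 3.33e-08; 4 of 29 positive adjusted over the list alone) and 1.34 for lymphocytes (camera adjusted p = 0.00618; 1 of 19 positive adjusted over the list alone), each with an adjusted p = 0.555 with an estimated correlation. The hepatocyte list had a median of -0.32 (camera adjusted p = 0.00356, adjusted p = 0.791 with an estimated correlation). Camera did not call the intestine list (median 3.15, adjusted p = 0.119) or, with a sign opposite to its median, the exocrine pancreas list (median 1.29, 30 of 30 members above 0, adjusted p = 0.256). Mean log2 CPM of the pancreas list was 6.66 at rest and 6.8 after exercise at 1 year, and 7.32 and 5.19 at 3 years. In all, 98 interactions were positive and 79 negative (edgeR quasi-likelihood test, adjusted p under 0.05). Without the libraries with intestinal reads 20 were called, 10 of them in common, and 2 of the 15 named genes passed. That fit kept 2 of 5 exercised 3-year fish, so a loss of power cannot be told apart from an effect of these reads. With intestine and pancreas covariates, on all 20 fish, 181 were called, 122 of them in common. Without resting 1-year replicate 1 or 2 the count was 78 and 68, without exercised 1-year replicate 1, 2, 3 or 5 it was 98, 87, 58 and 74. Without resting 3-year replicate 1, 2 or 5 it was 109, 112 and 95, and without exercised 3-year replicate 1, 2 or 5 it was 105, 110 and 85.

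Across 18079 genes, which are not independent replicates, the exercise effects at 1 and 3 years had a Pearson correlation of 0.127 and a Spearman correlation of 0.08. Of 100 draws of the exercise labels within each age, the real one included, 60 gave an absolute Pearson correlation as large. Without exercised 1-year replicate 4 the correlation was -0.176, and without resting 1-year replicate 5 it was 0.404. The age effect at rest and the exercise effect at 3 years, which share the resting 3-year fish, had a Pearson correlation of -0.243 and a Spearman correlation of -0.274. Unchanged groups gave a median of -0.521, with 95% of 1000 simulated values between -0.87 and 0.203. The covariance was -0.12 beside a simulated -0.188, and with the resting 3-year fish split into parts of 2 and 3 the correlation had a median of -0.008, from -0.211 to 0.359 over 20 splits. It was 0.074 without resting 1-year replicate 5.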

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

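Of the tests in this part, the fit with intestine and pancreas levels as covariates and the fit without the 7 libraries that hold intestinal reads were chosen only after the data had been seen.

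In each group of 5, a library was marked where its gap to the nearest other, divided by the range of the group, was above 0.71. Chance marks about 1 in 20 groups, or 36 of the 711 tested, and 48 were marked. Resting 1-year replicate 5 accounted for 10 and exercised 1-year replicate 4 for 9, both of them libraries with intestinal reads. Exercised 1-year replicate 4 was highest in total counts (gap ratio 0.84) and lowest in the share of the 10 most abundant genes (0.84), the hepatocyte list (0.836), the growth hormone and IGF list (0.739), C18H11orf58 (0.796), ASNS (0.835) and sat2a.2 (0.735). It was also highest in hamp (0.715) and cd74a (0.718). Resting 1-year replicate 5 was lowest in the hepatocyte list (0.853), the cytosolic ribosome list (0.759), EIF2AK3 (0.713), cyp2k31 (0.812) and MAF (ENSDARG00000076520; 0.747). It was highest in the intestine (0.799), cell cycle (0.733) and interferon lists (0.967), PPARGC1A (0.894) and BAZ2B (0.719).

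Among resting 1-year fish, replicate 2 was also highest in CDC42BPA (ENSDARG00000016464; 0.836) and replicate 3 lowest in sat2a.2 (0.783). Among exercised 1-year fish, replicate 1 was highest in the fatty acid synthesis list (0.818) and lowest in ZBTB16 (0.791) and PDK4 (0.826). Replicate 2 was lowest in MAPK14 (ENSDARG00000000857; 0.815), tefa (0.764) and crp1 (0.893) and highest in SUFU (0.906), and replicate 5 was lowest in zbtb16b (0.932). In resting 3-year fish, replicate 1 was highest in HSPA5 (0.824), FDPS (0.711), SEL1L (0.714), sat2a.2 (0.957) and cyp2ad2 (0.742). Replicate 2 was highest in sult3st4 (0.778) and POLR1B (0.76) and lowest in cyp2k31 (0.812). Replicate 4 of that group was lowest in EIF2AK3 (0.722), and replicate 5 was lowest in the cholesterol synthesis list (0.733) and IRS2 (ENSDARG00000037099; 0.716) and highest in cry3b (0.717). In exercised 3-year fish, replicate 1 was lowest in g6pc1a.1 (0.741), replicate 2 was highest in c1qc (0.718) and rims2b (0.843) and lowest in GFM2 (0.87). Replicate 3 was highest in GNL2 (0.726) and MAF (ENSDARG00000076520; 0.747), and replicate 5 was highest in RHBDF1 (ENSDARG00000036541; 0.729).

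The exercise effect differed between ages, by the interaction term of the edgeR quasi-likelihood test, for 15 named genes. The difference (log2, 3 years minus 1 year) was positive for RHBDF1 (ENSDARG00000036541; 2.50), MYO18A (ENSDARG00000075752; 2.1), ACBD3 (2.2), EIF2AK3 (2.4), RREB1 (ENSDARG00000063701; 2.14), SYNE1 (1.68), dnajc3b (2.29), HSPA5 (3.66) and DNAJB9 (ENSDARG00000016886; 4.27). It was negative for fbxw11a (-2.32), hnf4b (-2.16), SLC49A4 (-1.50), rims2b (-3.85), PSMD5 (-1.31) and PSMB5 (-0.78).

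Unfolded protein response transcripts were lower after exercise at 1 year, with a median log2 fold change of -1.09 over the list. Mean log2 CPM of the list was 5.82 in the resting 1-year fish and from 4.59 to 4.96 in the other groups. The falls with exercise at 1 year and with age at rest therefore share those resting fish and are not separate results. Reads from intestine or exocrine pancreas are argued against as the whole cause, since the median was -0.98 at its nearest to 0 over the fit with both as covariates and the fit without the 7 libraries. The median was -0.76 without resting replicate 1, the nearest to 0 on leaving out 1 of the 10 fish, and -1.11 with RLE size factors, which argues against 1 deviating fish and against scaling by a few abundant genes. Leaving out 1 fish cannot show how much of the size rests on 2 fish together. Mean log2 CPM of the list was 6.46 and 6.15 in resting replicates 1 and 2. It was from 5.34 to 5.60 in the other resting fish and from 4.69 to 5.15 in the exercised ones. A response of young liver to exercise is a hypothesis that stays open, as do feeding state and time of collection, which the labels do not give.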

How the results depend on the processing

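The settings without the libraries with intestinal reads, with intestine and pancreas covariates and with rescaled RPKM, and the correlations with 1 library left out, were chosen after seeing the data. Over 7960 values of 253 named gene and contrast pairs, 0 changed direction. In 696 of them a pair that passed as reported was no longer past the threshold. The genes were named from the same counts for a small p or a large fold, and 5060 of the values leave out 1 library. A change of direction was therefore unlikely from the start, and its absence does not show robustness. Counts for exercise at 1 year (515), exercise at 3 years (0), age at rest (632), age after exercise (1657), exercise averaged (353), age averaged (2233) and the interaction (177) stayed within 1.5 times with RLE size factors and with limma-voom. With the DESeq2 Wald test they were 1046, 456, 1298, 2739 and 972 for the first 5, and 573 for the interaction. With 1 surrogate variable exercise at 1 year had 975 calls, age at rest 1310, age averaged 3398 and the interaction 290. Intestine and pancreas covariates gave 824 for exercise at 1 year, 1105 for age at rest and 217 for exercise averaged, and pancreas and erythrocyte covariates gave 215 for exercise averaged. No low count filter gave 199 for exercise averaged and 100 for the interaction, and the stricter filter gave 6 for exercise at 3 years and 542 for exercise averaged. Fitted on the 2 groups alone, exercise at 1 year had 298 calls and age at rest 141. Without the libraries with intestinal reads the counts were 185 for exercise at 1 year, 2 for exercise at 3 years, and 437 for age after exercise. They were 6 for exercise averaged, 1450 for age averaged and 20 for the interaction, with 13 fish in that fit. The cause was not tested for these differences.

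Limma-trend on deposited RPKM, whose totals belong to other libraries, gave 194 for exercise at 1 year, 722 for age after exercise (207 higher, 515 lower), 136 for exercise averaged (112 higher, 24 lower). It gave 1227 for age averaged (252 higher, 975 lower) and 31 for the interaction (22 positive, 9 negative). Age at rest had 55 higher and 386 lower. On rescaled RPKM it gave 293 for exercise at 1 year (199 higher, 94 lower), 23 for exercise at 3 years (19 higher, 4 lower) and 901 for age after exercise (493 higher, 408 lower). It gave 1377 for age averaged and 56 for the interaction, and exercise averaged had 455 higher and 35 lower. Of 245 gene list tests 97 were called, 5 with an estimated correlation in camera and 33 with fry. Fry called 1 list for exercise at 1 year, the unfolded protein response (fry adjusted p = 0.0395), and 2 for exercise at 3 years. It called 6 for age at rest and 11 for age after exercise, oxidative phosphorylation among the latter (fry adjusted p = 0.00116). For exercise averaged, age averaged and the interaction fry called 1, 12 and 0.

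Leaving out 1 library in turn gave 240 to 614 calls for exercise at 1 year, 0 to 22 for exercise at 3 years, and 239 to 840 for age at rest. The ranges were 866 to 2515 for age after exercise, 140 to 657 for exercise averaged, 1684 to 3175 for age averaged and 58 to 216 for the interaction. The correlation of the exercise effects ranged from -0.176 to 0.404 and that of the age effect at rest with the exercise effect at 3 years from -0.425 to 0.074. No paired analysis was possible because the replicate numbers only follow the order of the samples.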

Other observations

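Of the tests in this part, those of time of day for the clock genes, and those of intestinal reads and of 1 deviating fish for the lipid synthesis genes, were chosen only after the result was seen, as were the settings that treat intestinal reads and the count of splits for single lists.

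Other gene groups differed between 3-year and 1-year exercised fish in edgeR's quasi-likelihood test. Gluconeogenesis and glycogen genes had 3 of 20 members lower, or 7 adjusted over the list alone (camera adjusted p = 0.00105; adjusted p = 0.149 with an estimated correlation). These were pck2 at -1.26, g6pc1a.1 at -1.2 and PC (ENSDARG00000098766) at -1.11. Of 16 glucocorticoid responsive genes 5 fell and 1 rose, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.03; adjusted p = 0.401 with an estimated correlation). DDIT4 had -3.83, PER1 (ENSDARG00000056885), also a clock gene, -3.32, tsc22d3 -1.84 and nfkbiaa 2.06. Interferon stimulated genes rose in 4 of 33 cases, also 4 adjusted over the list alone (camera adjusted p = 0.00059; adjusted p = 0.553 with an estimated correlation). They were irf9 at 0.78, irf1b at 1.38 (0.77 without exercised 3-year replicate 5, not called), helz2b at 1.12 and mxc at 3.09. Mean log2 CPM of this list was 3.4, 3.9 and 4.0 in exercised 3-year replicates 1, 2 and 5, which held intestinal reads. It was 2.1 and 3.3 in replicates 3 and 4 of that group. At 1 year it was 2.6 and 3.3 in exercised replicates 3 and 4, which held such reads, and from 1.6 to 2.2 in the others. Whether these reads account for the rise was not tested. The lipoprotein genes apoa4b.1 and apoc2 fell by 1.57 and 0.75, the called 2 of 26 (camera adjusted p = 0.0265; adjusted p = 0.141 with an estimated correlation). Of 13 genes in the cholangiocyte list 2 rose, also 2 adjusted over the list alone, with ANXA4 at 0.62 (camera adjusted p = 0.00818; adjusted p = 0.15 with an estimated correlation).

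Averaged over exercise, age also changed 4 of 25 acute phase genes, 3 of them upwards, or 5 up and 1 down adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.649 with an estimated correlation). LECT2 (ENSDARG00000090889; 0.98) and serpina1l (1.28) were among the rises. Averaged over ages, the cytochromes cyp2ad2, cyp2ad3 and cyp2ad6 fell with exercise by 1.17, 0.78 and 1.45, the called 3 of 43 xenobiotic metabolism genes (camera adjusted p = 0.0312; adjusted p = 0.819 with an estimated correlation). The heat shock genes BAG3 and HSF2 fell by 1.19 and 0.74, the called 2 of 27, or 5 adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.819 with an estimated correlation).

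Sterol and fatty acid synthesis transcripts were lower at 3 years at rest, with a median log2 fold change of -1.59 over both lists. It was -1.61 at its nearest to 0 with intestinal reads treated in either way, -1.41 without resting 1-year replicate 1, the value nearest to 0 on leaving out 1 of 10 fish, and -1.62 with RLE size factors. These values argue against reads from intestine or pancreas, 1 deviating fish and scaling as the whole cause. Age itself stays open and untested, and feeding state, which the labels do not give, may also differ between the groups.

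Clock transcripts differed between ages averaged over exercise, and a different time of day at collection is a candidate explanation. Genes taken by name to peak with bmal1 (9 genes, median 0.90, 4 called higher and 0 lower) and genes taken to have the opposite phase (15 genes, median -1.01, 9 called lower and 0 higher) moved apart, as with a shift of phase. Phases were not measured in these fish. Members that went the other way, none called, were npas2 (-0.94) and nfil3-6 (-0.72) in the first set. In the second they were nr1d4a (1.43), HLF (0.57) and PER2 (0.35). Reads from intestine or pancreas are argued against, since 15 of the 17 called clock genes were called in the fit that kept fewest. No collection time is given in the labels, and a change of the clock with age stays open and untested.

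Other splits of the same fish, 100 per contrast with the real one included, asked how often a grouping calls as many genes as the real one. Fewer than 5 did for exercise at 1 year (515 genes, 1 split as large, highest other 7) and age at rest (632, 1 split, highest other 601). So it was for age after exercise (1657, 2 splits, highest other 2211) and exercise averaged (353, 1 split, highest other 193). It also held for age averaged (2233, 2 splits, highest other 3992) and the interaction (177, 3 splits, highest other 2032). No correction was made over the 7 contrasts, so these counts do not exclude chance. For exercise at 3 years no gene was called, which each of the 100 splits reaches by construction (highest other 11), so this test says nothing about chance there. For the interaction the highest other split called several times the real count, which points to a structure of the samples. Its groups held 3, 0, 0 and 4 of the libraries with intestinal reads, all of them in the pair of groups that the interaction adds, and no test linked these libraries to its calls. The highest other splits also exceeded the real count for age averaged, with 0 and 1 of these libraries in its 1-year and 2 and 4 in its 3-year groups, and for age after exercise, with 1 against 4 in the groups compared. The number of called lists was reached by fewer than 5 splits for exercise at 3 years (21, 2 splits, highest other 22), again without correction over contrasts. With an estimated correlation 0 of the 35 lists were called there, and fry called 2. The number of called lists cannot be told from chance for exercise at 1 year (8, 93 splits, highest other 21), age at rest (10, 87 splits, highest other 22) or age after exercise (19, 20 splits, highest other 24). Nor can it for exercise averaged (12, 70 splits, highest other 21), age averaged (15, 41 splits, highest other 22) or the interaction (12, 67 splits, highest other 22). Of 245 list tests 97 were called by camera, and the counts of splits for single lists are not corrected for that number. With the real split included, the smallest count that can be reached is 1. For single lists called by camera, fewer than 5 of the 100 splits gave a p as small, the real one included, in the following cases. They were the unfolded protein response for exercise at 1 year (1) and averaged (1), and cholesterol synthesis (1), fatty acid synthesis (1) and the clock (4) for age at rest. For age after exercise they were fatty acid synthesis (1), fatty acid oxidation (2), oxidative phosphorylation (2) and the myeloid list (4). For age averaged they were cholesterol synthesis (1), fatty acid synthesis (1), the clock (2), oestrogen responsive genes (3), gluconeogenesis (3) and oxidative phosphorylation (4), and for the interaction fatty acid oxidation (2). Other called lists were reached by 5 or more, such as cholesterol synthesis for exercise at 1 year (19), the unfolded protein response for age at rest (6) and the myeloid list for age averaged (9). This held for each of the 21 lists called for exercise at 3 years, among them the proteasome (7), the cytosolic ribosome (10) and the hepatocyte list (26). The correlation of both exercise effects cannot be told from chance either (0.127, 60 draws as large, highest other 0.731).

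Calls of age at rest and exercise at 1 year overlapped, with 40 genes higher in both (3.1 from independent lists) and 91 lower in both (6 from independent lists). Both contrasts share the resting 1-year fish. Their effects had a Pearson correlation of 0.231 across 18079 genes, beside a median of 0.537 for simulated unchanged groups (95% from -0.163 to 0.872). The covariance was 0.083 beside a simulated 0.194, with a median correlation of -0.163 with the resting 1-year fish split. The excess over either value is not a measure of a shared effect.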
